A study of Mus musculus with 4 samples.

How the data were processed

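Gene expression was measured in mouse primary osteoblasts, entered as pre-osteoblasts under cell type in the labels. The design crossed BMP2 (200 ng/ml or none) with LOXL2 (4 µg/ml or none) over 72 h in 10% serum, with 1 single-colour Agilent array per treatment and 4 arrays in all. Per the labels, 100 ng of total RNA was amplified and labelled with Cy3. The file headers place the 4 arrays on 1 slide with 1 scan time, so slide and scan did not differ between treatments. Array position and treatment cannot be told apart, because each treatment occupied 1 position. The labels do not say whether the 4 cultures came from separate cell preparations.

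The deposited scanner files give an intensity for each spot, made by the authors with Feature Extraction 10.7.3.1 per the submitters' processing notes. Per the file headers, this processing subtracted local background, removed spatial trends and put a surrogate value in place of signals not above background. The deposited value table holds 1 intensity per probe and array on the linear scale, with no scaling between arrays. It was checked against the scanner files and equalled the mean processed signal over a probe's spots, within 0.1%, for 99.52% to 99.53% of probes. No other step by the authors is stated.

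Each array held 62976 spots, of which 59305 were not controls and covered 55681 probes. The processed spot signals were put on the log2 scale, and the 75th percentile over the non-control spots of the array was subtracted. Spots that the scanner software had marked as non-uniform or as population outliers were left out, 109 to 144 per array. No spot was saturated. The spots of a probe were averaged, and a probe was kept where it was well above background on at least 2 of the 4 arrays. Probe names were brought to current symbols through a RefSeq table of the GRCm38.p6 assembly, used for names only. The accessions of 26762 probes were found there, and 28919 probes kept the name in the file. The probe with the highest mean over the 4 arrays represented a gene, which left 24041 genes, 14960 with a symbol and 9081 with an identifier only. Of these, 22609 were well above background on all 4 arrays. Probe positions are those of the file, on mm9 per the file headers.

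Signal over background sets the depth of an array. On the untreated, LOXL2, BMP2 and combined arrays, 36350, 36890, 35799 and 36043 spots were well above background. Over probes printed on 10 spots, the median standard deviation of the log2 signal was 0.0673, 0.0664, 0.0645 and 0.0654, which covers spot error within an array and not variation between cultures. The number of arrays limits the precision of every value.

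The effects of BMP2 and of LOXL2 were fitted together in an additive model with limma 3.58.1 under R 4.3.3, and tables were read with the data.table package, version 1.17.8. The model leaves 1 residual degree of freedom per gene, which is the interaction of the 2 proteins, and the empirical Bayes step added 1.72. The tests were two-sided, and p-values were adjusted over the 24041 genes by the Benjamini-Hochberg method with a threshold of 0.05. The median standard error of an effect was 0.0615 on the log2 scale. A gene whose response to one protein depends on the other has a large error in this fit. Differences between single arrays, and the difference of differences, have no test, because the full model leaves no residual degree of freedom. They are given as values, with the number of genes that independent lists would share. The 2 BMP2 differences (without and under LOXL2) share no array, and neither do the 2 LOXL2 differences.

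Where a gene was below background on every array of one side, its fold is a lower bound. The dim side was set to its own value or to the lowest intensity above background on that array (12.9 to 14.6), whichever was higher, and the result is written as at least N-fold. Medians of the gene lists did not move when such members were set at their bounds.

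Gene lists were tested with camera in limma at a preset correlation between genes of 0.01, adjusted over 31 lists for each protein, and again with a correlation estimated from the residuals. The second form tests on the 1 residual degree of freedom and has little power. The lists covered BMP-SMAD targets, BMP ligands and receptors, osteoblast transcription factors, osteoblast matrix, collagens, lysyl oxidases, matrix proteases, the Wnt, Notch, TGF-beta, hedgehog, FGF and IGF pathways, epithelial-mesenchymal transition, osteoclast regulators, cell cycle, interferon, NF-kB, hypoxia, ER stress, sterol synthesis, heat shock and reference genes. Markers of osteocytes, chondrocytes, adipocytes, skeletal muscle, leukocytes, osteoclasts, endothelium, tendon and fibroblasts, and nerve and glia were listed as well, and no gene was in more than 1 list. For each pair of arrays, a list's median was ranked among 10000 random lists of the same size matched on mean expression. The gene calls of each list were also adjusted over the list alone.

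The lists, the model, the filters, the alternatives and the rule for naming genes were chosen before the data were examined. For BMP2 the rule took the 12 largest rises and the 12 largest falls among genes past the threshold and at least 2-fold different the same way in both LOXL2 backgrounds. For LOXL2 it took the 10 genes highest and the 10 lowest in both BMP2 backgrounds by the smaller of the 2 differences. For each single LOXL2 difference and for the difference of differences, it took the 5 highest and the 5 lowest genes above background on all 4 arrays. It also took up to 4 members of each list by the size of the fitted change, and 24 genes of the BMP, lysyl oxidase, bone and cartilage programmes. Identifiers standing in for a symbol were counted and not named. Named outside the rule, after their values were seen, were Epyc, Matn4, Col11a1, Adm, Pdgfrb, Actc1 and the myosin genes other than Myh1.

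The alternatives were quantile normalization, median centring, normexp background correction of the mean signal with an offset of 50, the deposited value table, no filter on dim probes, a filter for all 4 arrays, the mean of a gene's probes, eBayes with trend and robust settings, the other factor left out of the model (2 residual degrees of freedom), fold thresholds of 1.5 and 4, and an estimated correlation for the lists. The fit was tested on simulated data of 24041 genes. With 5000 genes changed, 74.6% of 1.5-fold, 91.1% of 2-fold and 97.1% of 4-fold BMP2 changes were recovered, with 184 unchanged genes called. For LOXL2 these shares were 76.7%, 90% and 97.5%, with 183 unchanged genes called and 3 recovered genes given the wrong direction. With 200 genes changed, 0% were recovered at any of these folds for either protein, so a small set of changed genes cannot be seen with 4 arrays. Of 200 simulated lists, all 10 shifted by 0.2 on the log2 scale were called, as were 2 of the unshifted lists. The simulated genes varied independently, so this does not cover lists whose genes move together. No sample was left out.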

Results

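Expression in mouse primary osteoblasts was compared between 4 treatments of 72 h: none, LOXL2, BMP2, and both proteins. BMP2 is a growth factor that drives cartilage and bone formation, and LOXL2 is a secreted lysyl oxidase that cross-links collagen and elastin. The design text gives the purpose as finding factors that govern the differentiation of osteoblasts under BMP2. Each treatment was measured on 1 array, so no treatment was replicated, and every fitted effect rests on 2 arrays with a protein against 2 without it.

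The arrays were alike in depth. Spots well above background made up 61.3% of spots on the untreated array, 62.2% with LOXL2, 60.4% with BMP2 and 60.8% with both proteins. The 75th percentile of the intensity was 710.5, 723.7, 725.4 and 742.9 in the same order. Across genes, Pearson's r was 0.9967 between the untreated and LOXL2 arrays and 0.9968 between the BMP2 and combined arrays. Between the untreated and BMP2 arrays it was 0.9841. Genes are not independent replicates, and these coefficients describe the arrays only.

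To determine which genes BMP2 changed, arrays with and without the protein were compared with LOXL2 in the model. BMP2 raised the hypertrophic cartilage collagen Col10a1 by 8.34 ± 0.38 (fitted log2 change ± SE, limma adjusted p = 0.0206), and Col10a1 was below background on the untreated array. Between the 2 arrays with LOXL2, both above background, it differed by 8.95. Ihh, the hedgehog ligand of prehypertrophic chondrocytes, rose by 5.88 ± 0.19, the cartilage proteoglycan Snorc by 5.87 ± 0.44 and the hedgehog-responsive transcription factor Gli1 by 5.55 ± 0.27. Panx3, a channel protein of bone and cartilage, rose by 4.55 ± 0.20, and Meltf, a membrane iron-binding protein, by 5.07 ± 0.42. The osteoblast transcription factor Sp7 rose by 2.23 ± 0.05 and osteocalcin, Bglap, by 3.60 ± 0.13. Adjusted p for these genes ran from 0.0206 to 0.0282, that of Meltf. Among genes below background without BMP2, the R-spondin receptor Lgr6 was at least 13.8-fold higher with it, the protease inhibitor Spink5 at least 16.6-fold, the transporter Slc10a4 at least 12.6-fold, the inositol phosphatase Inpp5j at least 10.1-fold, the transcription factor Foxa2 at least 7.95-fold and Trarg1, a regulator of glucose transporter traffic, at least 7.38-fold.

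The largest falls included the R-spondin receptor Lgr5, which fell by 6.42 ± 0.11, and the secreted Wnt modulator Sfrp2, which fell by 5.07 ± 0.12. Prostaglandin D synthase, Ptgds, fell by 5.11 ± 0.07, and the retinoic acid binding protein Crabp1 fell by 5.09 ± 0.10. The myosin heavy chain Myh1, whose paralogs are close in sequence, fell by 5.01 ± 0.06, Tmem178 fell by 4.93 ± 0.13 and the carboxypeptidase Cpb1 fell by 4.91 ± 0.05. Adjusted p was 0.0206 for each of these 7 genes. Of genes below background with BMP2, the matrix protein Egfl6 was at least 30.0-fold lower, the tetraspanin Tspan8 at least 24.8-fold, the neuropeptide Vip at least 15.1-fold, the angiotensin receptor Agtr1b at least 10.4-fold and Mup18, a major urinary protein, at least 8.01-fold. On mm9, the probe of Col10a1 lies on chromosome 10 from 34116831 to 34116890, that of Ihh on chromosome 1 from 74991906 to 74991965, that of Lgr5 on chromosome 10 from 114887403 to 114887462 and that of Sfrp2 on chromosome 3 from 83577864 to 83577923.

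In limma, 4883 of 24041 genes changed with BMP2 at an adjusted p under 0.05, of which 2485 rose and 2398 fell. The share that rose depended on the scaling. It was 50.9% here, 47% with quantile normalization and 60.7% with median centring, so the even split is not a result. At an unadjusted p under 0.05 there were 10323 genes, against 1202 by chance. A fitted change of at least 2-fold was found for 1268 of the called genes, 545 up and 723 down. Of the called genes, 106 were below background without BMP2 and higher with it, and 226 were below background with BMP2 and lower. The smallest adjusted p was 0.0206, so many of the named genes share it. With no filter on dim probes 0 genes passed (smallest adjusted p 0.09, 9259 genes at an unadjusted p under 0.05), while normexp background correction gave 9086 genes and eBayes with trend and robust settings 10389.

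The response was also read from single pairs of arrays, which have no test. Without LOXL2, 1621 genes differed at least 2-fold with BMP2 (714 higher and 907 lower), and under LOXL2 1609 genes did (687 higher and 922 lower). In both pairs 496 genes were higher and 658 lower, where independent lists would share 20.4 and 34.8. Only 21 genes went in opposite directions, against 53.3. Across genes the BMP2 differences of the 2 pairs had a Pearson's r of 0.811 and a Spearman's rho of 0.741, and 79.4% of genes had the same sign. Lgr5 was lower by similar amounts in both pairs, with differences of -6.25 and -6.58, and Sp7 was higher, with 2.24 and 2.22.

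**Figure D1:**
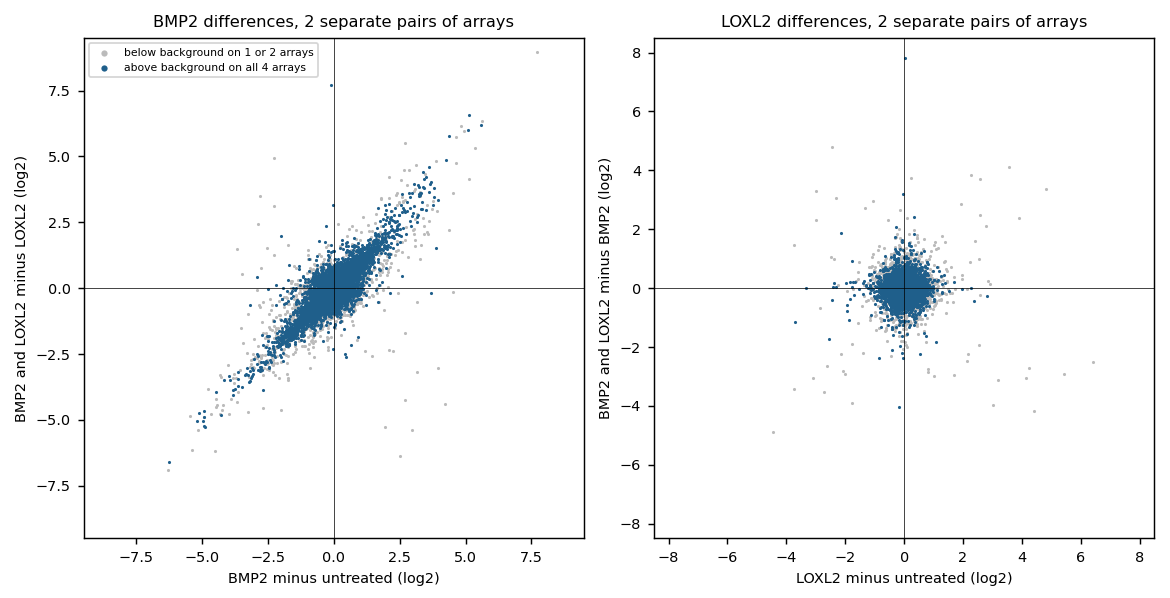
Each point is a gene; the left panel plots the log2 BMP2 difference under LOXL2 against that without LOXL2, and the right panel the log2 LOXL2 difference under BMP2 against that without BMP2, with genes above background on all 4 arrays in blue and the others in grey. Pearson's r across all 24041 genes is 0.811 on the left and 0.0438 on the right.

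Cartilage and bone genes were examined by list. Of 24 chondrocyte genes measured, 16 rose and 3 fell (17 and 4 adjusted over the list alone), with a median change of 2.26. The camera test gave an adjusted p = 0.000204 at the preset correlation and an adjusted p = 0.846 with an estimated correlation. The major cartilage collagen Col2a1 rose by 2.29 ± 0.13, the proteoglycan Acan by 3.54 ± 0.20 and the transcription factor Sox9 by 0.73 ± 0.06, while Matn1, a cartilage matrix protein below background without BMP2, was at least 6.89-fold higher. Epyc fell by 1.32, Matn4 by 1.65 and Col11a1 by 0.36; Epyc and Matn4 encode cartilage matrix proteins and Col11a1 a minor fibrillar collagen. On the same arrays leukocyte markers had a median of -0.51 and tendon and fibroblast markers a median of -0.79. Of 16 osteoblast transcription factors, 9 rose and 2 fell (10 and 2 adjusted over the list alone), with a median of 0.45. Camera gave an adjusted p = 0.0146, with an adjusted p = 0.846 with an estimated correlation. Beside Sp7, the Wnt effector Tcf7 rose by 1.99, Mef2c by 1.42 and the homeobox gene Dlx5 by 1.40. For Runx2, the master regulator of osteoblasts, the change was 0.08 with an adjusted p = 0.366, and its 3 probes ran from 0.08 to 0.725.

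Among 24 genes of osteoblast matrix and mineralisation, 9 rose and 4 fell (11 and 7 adjusted over the list alone), with a median of 0.20 and a camera adjusted p = 0.444. The sphingomyelinase Smpd3 rose by 4.11, bone sialoprotein, Ibsp, by 2.53 and alkaline phosphatase, Alpl, by 1.87. Bglap2 rose by 3.47 and Bglap3 by 3.36; both are near-identical in sequence to Bglap. Osteopontin, Spp1, differed by 0.77 with an adjusted p = 0.0595, and the main bone collagen Col1a1 by -0.06 with an adjusted p = 0.447. In the osteocyte list 3 of 9 genes rose and 1 fell (4 and 1 adjusted over the list alone), with a camera adjusted p = 0.477. The receptor phosphatase Ptprz1 rose by 0.74 and the membrane mucin Pdpn fell by 0.43. In the hedgehog and PTHrP list 3 of 9 genes rose (4 rose and 1 fell adjusted over the list alone), the median was 0.19, the mean 1.39 and the camera adjusted p = 0.117. The 3 were Gli1, the inhibitor Hhip with 3.28 and the receptor Ptch1 with 2.85, all direct targets of the pathway.

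**Figure D2:**
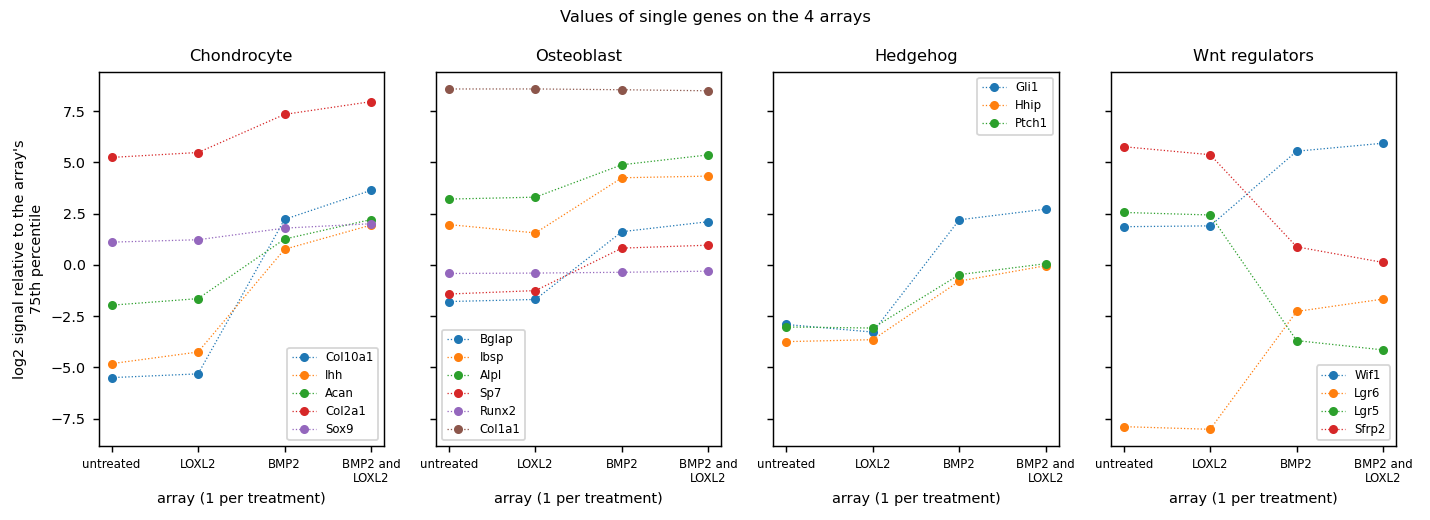
Points are log2 signals relative to the array's 75th percentile for single genes on each of the 4 arrays, with dotted lines joining the points of a gene and 1 array per treatment. Col10a1, Ihh, Gli1 and Lgr6 lie higher on both arrays with BMP2, Lgr5 and Sfrp2 lie lower, and Col1a1 differs by -0.06 in the fit.

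Signalling genes moved in both directions. Among 22 BMP-SMAD targets 8 rose and 4 fell (9 and 8 adjusted over the list alone), with a median of 0.19 and a camera adjusted p = 0.563. The list's BMP2 median was 0.0215 without LOXL2, at percentile 46.9 of random lists, and 0.355 under LOXL2, at percentile 100. The transcriptional repressor Hey1 rose by 3.80, the BMP antagonist Grem1 by 2.71, the netrin receptor Unc5b by 1.88, and the inhibitory Smads Smad6 and Smad7 by 1.08 and 0.62. Of the inhibitors of differentiation, Id1 rose by 0.78 (adjusted p = 0.0416), while Id2 differed by 0.16 (adjusted p = 0.263) and Id3 by 0.35 (adjusted p = 0.0729). The BMP antagonist Nog differed by 0.22 with an adjusted p = 0.352. The BMP family ligand Gdf6 fell by 3.99 ± 0.44 and was below background on the array with both proteins, with a difference of -3.27 between the 2 arrays without LOXL2. Of 18 BMP ligands and receptors, 3 fell (1 rose and 5 fell adjusted over the list alone); the median was 0.06, the mean -0.22 and the test pointed down, with an adjusted p = 0.857. The ligand Bmp4 fell by 2.46, and endogenous Bmp2 differed by 0.39 with an adjusted p = 0.103.

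In the Wnt list 6 of 28 genes rose and 12 fell (9 and 12 adjusted over the list alone), with a median of -0.10 and a camera adjusted p = 0.406. The secreted inhibitor Wif1 rose by 3.86, while Lgr5 and Sfrp2 were among the largest falls. In the Notch list 5 of 9 genes rose and 1 fell (5 and 2 adjusted over the list alone), with a camera adjusted p = 0.309. The effector Hes1 rose by 1.10 and the ligand Jag1 by 0.81. Of 18 TGF-beta and contractile genes 5 rose and 9 fell (5 and 11 adjusted over the list alone), with a camera adjusted p = 0.13. The matrix protein Tgfbi rose by 2.02 and the ligand Tgfb1 by 1.48, while the smooth muscle genes Tpm1 and Cnn1 fell by 1.37 and 1.20, and the 6 probes of Tpm1 ran from -1.58 to -0.0869. In the list of epithelial-mesenchymal transition 1 of 11 genes rose and 4 fell (2 and 6 adjusted over the list alone), with a camera adjusted p = 0.0922. The tight junction gene Cldn1 was at least 3.31-fold lower and the epithelial cadherin Cdh1 at least 2.10-fold, and Snai1, a repressor of Cdh1, differed by 0.14 with an adjusted p = 0.157. Of 23 FGF and IGF genes 3 rose and 8 fell (4 and 10 adjusted over the list alone), with a camera adjusted p = 0.275. The receptor Fgfr3, which restrains chondrocyte growth, rose by 3.40, the binding protein Igfbp2 fell by 3.16 and Igfbp3 fell by 3.06.

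Matrix genes were split as well. Of 24 lysyl oxidase and collagen processing genes 8 rose and 6 fell (9 and 8 adjusted over the list alone), with a median of 0.05 and a camera adjusted p = 0.857. Lox fell by 1.03 ± 0.06 (adjusted p = 0.0239) and Loxl1 by 0.51 ± 0.05 (adjusted p = 0.034), while Loxl4 rose by 0.42 ± 0.05 (adjusted p = 0.0414). Endogenous Loxl2 differed by -0.16 with an adjusted p = 0.169 (its 3 probes ran from -0.425 to -0.165) and Loxl3 by 0.11 with an adjusted p = 0.272. The collagen hydroxylases P4ha2 and Plod2 rose by 1.29 and 1.12. Of 28 collagens and structural matrix genes 5 rose and 9 fell (9 and 11 adjusted over the list alone), with a camera adjusted p = 0.511. Col8a1, a short-chain collagen, fell by 2.49, the adhesive glycoprotein Thbs1 by 1.70, and the basement membrane collagen Col18a1 rose by 1.34. In the list of matrix proteases and inhibitors 2 of 18 genes rose and 7 fell (4 and 9 adjusted over the list alone), with a camera adjusted p = 0.0786. The stromelysin Mmp3 fell by 1.79, the aggrecanase Adamts5 by 1.53, and the inhibitor Timp3 rose by 1.55.

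Of 15 hypoxia and glycolysis genes, 14 rose and 1 fell, with the counts unchanged when adjusted over the list alone (14 and 1). The median was 1 and the camera adjusted p = 1.17e-05, with an adjusted p = 0.846 with an estimated correlation. The hypoxia-inducible gene Ndrg1 rose by 1.71, the carbonic anhydrase Car9 by 1.58 and the angiogenic factor Vegfa by 1.52, while the vasodilator peptide Adm fell by 1.21. In the list of ER stress and amino acid response 7 of 15 genes rose and 0 fell in limma (8 and 0 adjusted over the list alone), with a median of 0.44. Camera gave an adjusted p = 0.0011, and an adjusted p = 0.846 with an estimated correlation. The pseudokinase Trib3 rose by 1.77, the transcription factors Atf3 and Ddit3 by 1.40 and 1.04, and the disulphide isomerase Pdia4 by 1.04. Of 24 cell cycle genes 2 rose and 8 fell (3 and 17 adjusted over the list alone), with a median of -0.38. Camera gave an adjusted p = 0.00116, and an adjusted p = 0.846 with an estimated correlation. The mitotic cyclin Ccnb2 fell by 0.68 and the anaphase regulator Cdc20 by 0.61, and the cell cycle inhibitor Cdkn1a rose by 0.73. Leukocyte markers had a median of -0.51 and tendon and fibroblast markers a median of -0.79 on the same arrays.

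Other response lists were not called. In the interferon list 2 of 22 genes rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.548). Its BMP2 median was 0.527 without LOXL2, at percentile 100 of random lists, and -0.0196 under LOXL2, at percentile 23.5. In the NF-kB list 4 of 17 genes rose and 3 fell (5 and 7 adjusted over the list alone; camera adjusted p = 0.857), and cyclooxygenase-2, Ptgs2, rose by 1.37. In sterol synthesis 1 of 13 genes rose (0 adjusted over the list alone; camera adjusted p = 0.167). In heat shock and oxidative stress 5 of 13 rose and 2 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.406), with the metallothioneins Mt1 and Mt2 up by 0.71 and 0.87. Among 12 reference genes 2 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.431). The transferrin receptor Tfrc rose by 1.10 and B2m by 0.55, Actb fell by 0.34, and Gapdh differed by 0.31 with an adjusted p = 0.0607.

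Markers of other cell types were followed on the same arrays. Of 18 macrophage and leukocyte genes 0 rose and 8 fell in limma (0 and 9 adjusted over the list alone), with a median of -0.51. Camera gave an adjusted p = 4.8e-05, and an adjusted p = 0.846 with an estimated correlation. The mannose receptor Mrc1 fell by 1.55, Aif1 by 0.98, lysozyme, Lyz2, by 0.89 and the complement gene C1qc by 0.85. Of 13 tendon and fibroblast genes 1 rose and 6 fell (2 and 7 adjusted over the list alone), with a median of -0.79. Camera gave an adjusted p = 0.0292, and an adjusted p = 0.846 with an estimated correlation. The progenitor surface marker Cd34 fell by 2.88 and the matrix protein Dpt fell by 2.44, while the growth factor receptor Pdgfrb rose by 0.61. In each of the 2 pairs of arrays, the chondrocyte, osteoblast transcription factor, hypoxia and ER stress lists lay at percentile 99.95 or higher among random lists, and the leukocyte, tendon and cell cycle lists at 0.02 or lower. Lists that camera did not call came as far. The TGF-beta and contractile list lay at 0 in both pairs, matrix proteases at 0.11 and 0, and Notch at 99.97 and 99.68. These ranks therefore do not set the called lists apart.

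In the adipocyte list 2 of 13 genes rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.117). Of 12 skeletal muscle genes 1 rose and 3 fell (2 and 3 adjusted over the list alone); the median was 0.12, the mean -0.35 and the test pointed down, with an adjusted p = 0.857. Skeletal actin, Acta1, fell by 1.21 and the receptor subunit Chrna1 rose by 0.75. In the osteoclast list 2 of 8 genes rose and 1 fell (2 and 1 adjusted over the list alone); the median was -0.06, the mean 0.23 and the test pointed up, with an adjusted p = 0.874. The proton pump subunit Atp6v0d2 rose by 1.79. Of 8 osteoclast regulators 3 rose and 2 fell (4 and 4 adjusted over the list alone); the median was 0.01, the mean -0.15 and the test pointed down, with an adjusted p = 0.857. RANKL, Tnfsf11, rose by 0.99 and the semaphorin Sema3a fell by 1.94. In the endothelial list 2 of 8 genes rose and 2 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.68), and von Willebrand factor, Vwf, rose by 1.89. In the neural and glial list 3 of 8 genes rose and 2 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.474). The growth cone gene Gap43 fell by 2.04, and the 3 probes of Mbp ran from -2.43 to 0.03.

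**Figure D3:**
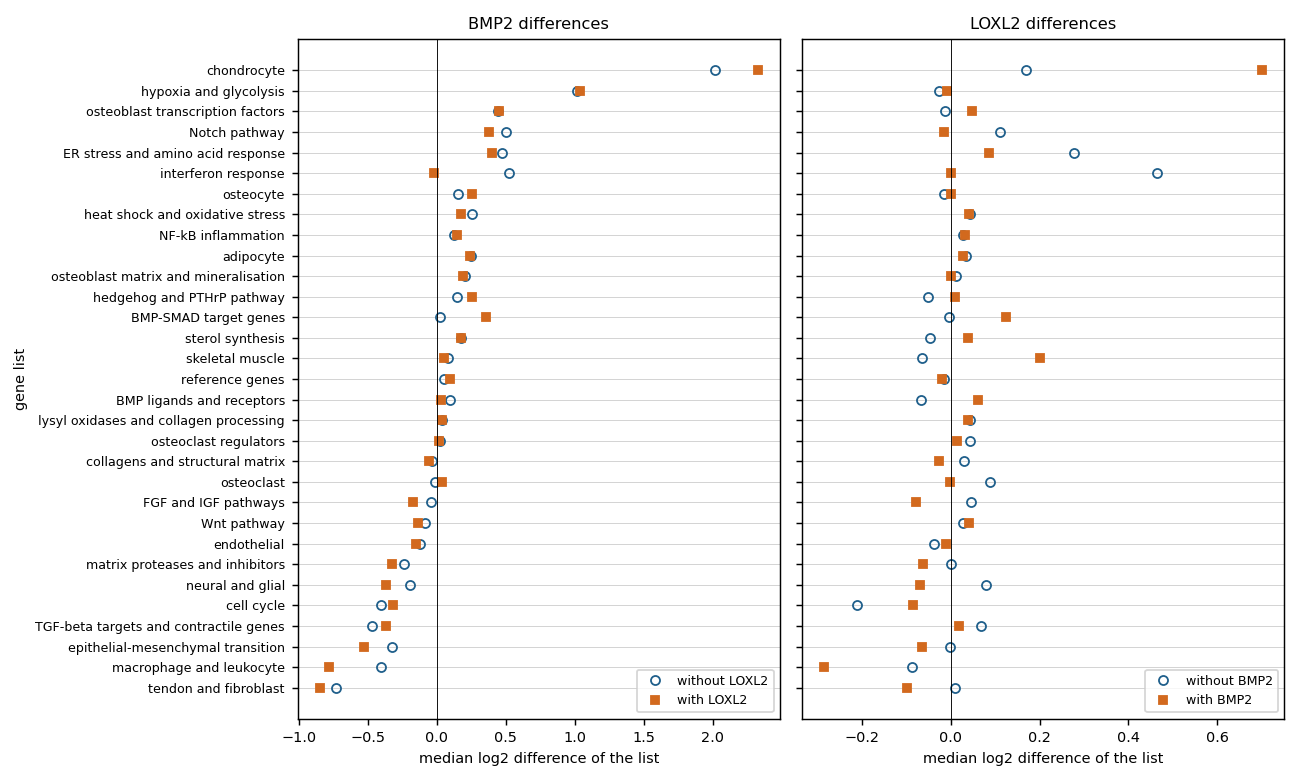
Each line is a gene list; points are the median log2 difference of its members with BMP2 (left, open circles without LOXL2 and squares with it) and with LOXL2 (right, open circles without BMP2 and squares with it), from 1 pair of arrays each. The chondrocyte list has the highest BMP2 medians (2.02 and 2.33), and its LOXL2 medians are 0.169 without BMP2 and 0.702 under it.

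To determine what LOXL2 added, arrays with and without LOXL2 were compared with BMP2 in the model. Among the lysyl oxidase genes, the LOXL2 effect was -0.01 ± 0.06 for Loxl2 (adjusted p = 0.973) and -0.04 ± 0.06 for Lox. It was larger for Loxl4, with 0.24 ± 0.05. Osteoblast genes had small effects, such as 0.04 for Runx2, 0.15 for Sp7, 0.29 for Bglap and -0.16 for Ibsp. Several chondrocyte genes had larger ones, with 0.87 ± 0.19 for Ihh, 0.80 ± 0.38 for Col10a1, 0.64 ± 0.20 for Acan and 0.43 ± 0.13 for Col2a1, each higher in both BMP2 backgrounds, while the chondrocyte regulator Sox9 had 0.16 ± 0.06, close to Sp7. The effect of Col10a1 rests partly on an untreated value below background, and its difference without BMP2 is a bound of at least 1.135-fold. None of these genes passed the test, and their adjusted p was 0.79 or more.

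In limma 0 of 24041 genes passed an adjusted p under 0.05 for LOXL2, with a smallest adjusted p of 0.48. At an unadjusted p under 0.05 there were 1485 genes (676 higher and 809 lower), against 1202 by chance. The eBayes fit with trend and robust settings gave 14 genes, 8 higher and 6 lower. With 200 genes changed in simulated data 0% were recovered, so that 0 calls do not exclude a set of changed genes of that size.

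By list, 6 of 31 were called for LOXL2 at the preset correlation, and 0 with an estimated correlation. The chondrocyte list was higher, with a median of 0.45, 18 of 24 genes higher in both BMP2 backgrounds and 0 lower in both. Its camera adjusted p = 2.05e-09, and its adjusted p = 0.904 with an estimated correlation. In ER stress and amino acid response 14 of 15 genes were higher in both backgrounds, with a median of 0.19 (adjusted p = 2.55e-06, and adjusted p = 0.904 with an estimated correlation), such as Trib3 with 0.27 and Pdia4 with 0.25. In the cell cycle list 16 of 24 genes were lower in both backgrounds and 0 higher, with a median of -0.12 (adjusted p = 6.6e-06, and adjusted p = 0.904 with an estimated correlation). The replication helicase subunit Mcm5 and the cyclin Ccnb1 each differed by -0.31. Both medians were nearer 0 under BMP2. The ER stress median was 0.278 without BMP2 and 0.0852 under it, and the cell cycle median -0.212 and -0.0855. Macrophage and leukocyte markers were lower, with a median of -0.19 and 10 of 18 lower in both backgrounds (adjusted p = 0.00271, and adjusted p = 0.904 with an estimated correlation). The macrophage receptor Adgre1 differed by -0.59 and C1qa by -0.41. These leukocyte values stand on the same arrays as the chondrocyte, ER stress and cell cycle values, and as the interferon and BMP-SMAD values below. Among random lists, the chondrocyte and ER stress medians lay at percentile 100 and the cell cycle median at percentile 0 in both backgrounds, and the leukocyte median at 2.81 without BMP2 and 0 under it. The list of lysyl oxidases and collagen processing, which was not called, lay at 99.3 in both.

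The interferon list was higher, with a median of 0.19 and 11 of 22 genes higher in both backgrounds (adjusted p = 0.00503, and adjusted p = 0.904 with an estimated correlation). The BMP-SMAD list had a median of 0.07 with 7 of 22 genes higher in both and 2 lower (adjusted p = 0.0216, and adjusted p = 0.904 with an estimated correlation). The interferon median lay at percentile 100 of random lists without BMP2 and 50.9 under it, and the BMP-SMAD median at 48.9 and 100. The interferon rise with LOXL2 alone and that with BMP2 alone both rest on the same untreated array, so they are not separate results. The other 25 lists had adjusted p from 0.104 to 0.855, among them lysyl oxidases and collagen processing (median 0.06) and osteoblast matrix (median 0.03). For the osteocyte list, collagens, the hedgehog list and osteoclast regulators the LOXL2 median was negative while the mean and the test pointed up. Adjusted over the list alone, 1 skeletal muscle gene (Actc1, cardiac actin, 0.62) and 1 osteoclast gene (Car2, a carbonic anhydrase near background) passed in limma, and 0 genes of any other list.

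Single pairs of arrays were compared for LOXL2 without a test. Without BMP2, 211 genes differed at least 2-fold (110 higher and 101 lower), and under BMP2 270 did (132 higher and 138 lower). Of genes above background on all 4 arrays these were 65 and 80, and with normexp background correction 27 and 35 genes. In both pairs 16 genes were higher and 16 lower, against 0.604 and 0.58 for independent lists, and 24 went in opposite directions against 1.19. Among the 32 genes shared in direction, 3 were above background on all 4 arrays, all lower. Independent lists allow neither for the larger spread of dim genes nor for the filter on 2 arrays. The excess over them is therefore not read as a response to LOXL2. Across genes the 2 LOXL2 differences had a Pearson's r of 0.0438 and a Spearman's rho of 0.0998, and 54.9% of genes had the same sign.

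Of the 20 named genes with the same direction in both pairs, most lay at or near background. The olfactory receptor Olfr350 was at least 3.54-fold higher with LOXL2, the transcription factor Etv2 at least 1.52-fold, the ligand Wnt3 at least 1.495-fold, Edaradd, an adaptor of ectodysplasin signalling, at least 1.42-fold, the lipid droplet protein Plin1 at least 1.18-fold and Car2 at least 1.11-fold. Below background on the untreated array, Foxa3, Cdh22, Olfr532 and Upk3bl were at least 1.18-fold, 2.08-fold, 1.99-fold and 1.34-fold higher without BMP2 and differed by 1.01, 0.87, 1.56 and 0.88 under it. The homeobox gene Obox1 was at least 3.27-fold lower (adjusted p = 0.542), the glucokinase regulator Gckr at least 2.08-fold, Dqx1 at least 1.76-fold and Olfr1 at least 1.36-fold. Tmed6, below background on the array with both proteins, differed by -1.76 without BMP2 and was at least 3.39-fold lower under it. Adcyap1r1 differed by -0.95 without BMP2 and was below background on both arrays with BMP2, which leaves no measured difference there. Above background on all 4 arrays were the lectin Clec4a2 (-1.47), the DNA helicase Brip1 (-1.02), Olfr1500 (-1.62) and Rnf151 (-0.82). None passed the limma test, with adjusted p of 0.542 or more.

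Among genes with a symbol and above background on all 4 arrays, those highest with LOXL2 without BMP2 included Slc35a5, a nucleotide sugar transporter family member (2.39), Igsf1 (1.38), Serpina1a (1.37) and Tmem178b (1.30). A further probe of Slc35a5 and one of Serpina1a, each above background on all 4 arrays, differed by 0.18 and 0.174. The lowest were the zinc transporter Slc39a9 (-2.45), Sh3rf2 (-2.42), A3galt2 (-2.38), Pik3c2g (-2.30) and the vomeronasal receptor Vmn2r67 (-2.15). Under BMP2 the highest were the kinase anchor Akap6 (2.43), Vmn2r67 (1.87), Palb2 (1.84), Npy4r (1.57) and Meltf (1.53). The lowest were the centromere factor Oip5 (-4.05), Olfr1500 (-2.39), the chemokine Cxcl10 (-2.25), the antiviral GTPase Mx1 (-1.82) and Arhgap25 (-1.63). Each is a difference between 2 single arrays with no replicate.

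Whether LOXL2 shifted the BMP2 difference was read from all 4 arrays, and the design leaves no test for it. The shift was at least 2-fold for 552 genes, 276 upward and 276 downward, of which 222 were above background on all 4 arrays. With normexp background correction 56 genes had such a shift. The chondrocyte genes Col10a1 and Snorc had shifts of 1.24 and 1.44, Ihh 0.61 and Acan 0.63, while Sp7 had -0.03 and Runx2 0.03. The shift of Col10a1 rests on an untreated value below background. Among genes with a symbol and above background on all 4 arrays, the largest upward shifts were 4.02 for Vmn2r67 and 2.67 for the amino acid transporter Slc38a3. The largest downward shifts were -3.88 for Oip5, -2.92 for Mx1, -2.81 for Slc35a5 and -2.79 for Cxcl10. A further probe of Slc35a5 had a shift of -0.03. Of 30 other probes of 19 genes with opposite LOXL2 differences, 11 showed the shift in the same direction and at least 0.5 in size.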

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

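The comparison with other probes of the same genes was chosen only after the result was seen. Genes picked for the largest shift of the BMP2 difference had LOXL2 differences far apart without and under BMP2, which the choice of genes alone would give. The values are the shift, followed by the LOXL2 difference without and under BMP2. Vmn2r67 had 4.02 (-2.15 and 1.87), Slc38a3 2.67 (-1.76 and 0.91), A3galt2 2.56 (-2.38 and 0.18), Sh3rf2 2.47 (-2.42 and 0.04) and Pik3c2g 2.34 (-2.30 and 0.04). For A3galt2, Sh3rf2 and Pik3c2g the difference under BMP2 lies within 1 standard deviation of that difference over genes (0.198), so it shows no reversal. Saa3 had -2.36 (0.74 and -1.61), Cxcl10 -2.79 (0.54 and -2.25), Slc35a5 -2.81 (2.39 and -0.43) and Mx1 -2.92 (1.10 and -1.82). These differences between backgrounds were not tested, since each rests on 4 single arrays.

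A probe deviating on 1 array could give such values. If so, other probes of the same gene should not show the shift. Of the 9 genes above only Slc35a5 has a further probe above background on all 4 arrays, and its shift was -0.03. The other 8 have none, which leaves a deviating probe open for them. Among 19 genes with opposite LOXL2 differences and a further probe above background on all 4 arrays, 11 of 30 such probes, or 36.7%, showed the shift in the same direction and at least 0.5 in size. For BMP2 changes of at least 2-fold, 241 of 308 other probes, or 78.2%, showed the BMP2 change in the same direction and at least 0.5 in size. These shares cannot be compared directly, since the shift is a difference of differences while the BMP2 change is a mean of differences. No share for random probes was computed. The share for LOXL2 leaves deviating probes open for many of these 19 genes without excluding a shift for the others, and a response of the cells was not tested.

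The interferon list and the BMP-SMAD list each had a LOXL2 median away from 0 in 1 background and near 0 in the other. The interferon median was 0.464 without BMP2 and -0.000465 under it (percentile 50.9 of random lists), and the median shift over its 22 genes was -0.418. The BMP-SMAD median was -0.00417 without BMP2 (percentile 48.9) and 0.124 under it, with a median shift of 0.111. Neither difference was tested. The interferon BMP2 median was likewise 0.527 without LOXL2 and -0.0196 under it. The interferon medians away from 0, for LOXL2 and for BMP2, share the untreated array and are not independent of each other. The BMP-SMAD medians away from 0, 0.124 for LOXL2 under BMP2 and 0.355 for BMP2 under LOXL2, share the combined array in the same way.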

How the results depend on the processing

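No alternative was added to those planned. Quantile normalization, median centring, the deposited value table and the mean of a gene's probes left all 15 comparisons within 1.5 times their counts or 0.1 of their correlations. Leaving out the other factor did so for the 4 counts of called genes. No named gene and no list reversed its direction where it had been called. The 13 list calls (7 for BMP2 and 6 for LOXL2) held under 7 alternatives and were lost with an estimated correlation, which left 0 for BMP2 and 0 for LOXL2. That setting estimates the correlation, at 0.681 for the chondrocyte list, 0.733 for ER stress, 0.42 for cell cycle, 1 for interferon and 0.0303 to 0.231 for the other called lists, against 0.01, and it also tests on the 1 residual degree of freedom. With 1 residual per gene, the estimate reflects only how many members have residuals of the same sign. That residual is the shift of the BMP2 difference, so the estimate is no measure of how genes vary together. The correlation and the degree of freedom were not tried apart for the called lists. The camera p also rose where the estimated correlation lay under 0.01, which argues for the degree of freedom there. With BMP2 it went from 0.0505 to 0.281 for the TGF-beta list (-0.0458). For osteoblast matrix (-0.0362) it went from 0.272 to 0.438. Over the 31 lists the lowest camera adjusted p was 0.846 for BMP2 and 0.904 for LOXL2, so this setting separates no list from the others. With BMP2, 4883 genes became 9086 with normexp, 0 with no filter and 10389 with trend and robust settings, and the 1268 genes changed at least 2-fold became 697 with normexp and 0 with no filter. For LOXL2 trend and robust settings gave 14 genes, 7 of them at least 2-fold. With no filter the prior standard deviation was 0.0818 over 35077 genes, against 0.0655. For the larger numbers of calls with normexp and with trend and robust settings the cause was not tested. Of the 4883 genes, normexp called 4659, quantile normalization 4077, median centring 4658 and the deposited values 4641. Of 160 genes named for BMP2, 133 lost their call with no filter, 9 with the mean of probes, 7 with quantile normalization, 3 with the deposited values and 1 with median centring. A call was gained by 17 with normexp, 5 with the filter for all 4 arrays, 1 with the mean of probes and 1 with median centring. Of 30 untested differences of named genes, 25 moved with normexp and 3 with the mean of probes.

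Counts of genes at least 2-fold different between single arrays moved with the filter, the background correction and the threshold. With normexp they were 708 for BMP2 without LOXL2, 726 under LOXL2, 591 in both, 27 for LOXL2 without BMP2, 35 under BMP2, 2 in both, and 56 for the shift. With no filter they were 3169 for BMP2 without LOXL2, 3255 under LOXL2, 1775 for LOXL2 without BMP2, 1513 under BMP2, 152 in both and 3019 for the shift, and the correlation of the BMP2 differences was 0.526. Above background on all 4 arrays they were 65 for LOXL2 without BMP2, 80 under BMP2, 3 in both and 222 for the shift. At 1.5-fold they were 3998, 3810 and 2722 for BMP2 (without LOXL2, under it, both), 816, 831 and 105 for LOXL2 (without BMP2, under it, both) and 1687 for the shift. At 4-fold they were 435, 423 and 307 for BMP2, 52, 55 and 15 for LOXL2 and 77 for the shift. The 2 thresholds and the 2 filters change these counts by their construction. The normexp offset of 50 lies near the median processed intensity of the arrays (45.39 to 46.64), so it shrinks differences of dim spots by construction as well. How much of the drop with normexp this makes was not tested. No paired analysis was possible because each treatment has 1 array, and leaving out an array leaves no residual degree of freedom. Signal near background limits the LOXL2 counts: of 211 and 270 genes, 65 and 80 were above background on all 4 arrays.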

Other observations

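Chosen only after the result was seen were the LOXL2 differences of genes that BMP2 moved strongly, the use of the scalings and of the pair without BMP2 for the chondrocyte genes, their closer matching, the tests of the other muscle genes and the comparison of Myh1 with Myh8. Genes that BMP2 moved strongly were set against their LOXL2 differences, leaving out the chondrocyte list. The 148 other genes raised at least 4-fold by BMP2 had a median LOXL2 difference of 0.179 without BMP2 and 0.325 under it, and 70.9% and 86.5% of them were higher with LOXL2. The 196 genes lowered at least 4-fold had medians of -0.116 and -0.114, and 30.6% and 29.6% were higher. Of genes above background on all 4 arrays, 95 raised genes had medians of 0.193 and 0.287 and 97 lowered genes -0.124 and -0.149. These are values from 1 pair of arrays each, without a test.

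Several myosin heavy chain genes were lower with BMP2, most of them on chromosome 11. On arrays with BMP2, Myh1 fell by 5.01 ± 0.06 and Myh8 by 4.79 ± 0.10, while Myh2 was at least 4.99-fold lower and Myh13 at least 2.06-fold. Myh4 was at least 4.89-fold lower with an adjusted p = 0.0504, and the embryonic form Myh3 differed by 0.43 with an adjusted p = 0.114. The non-muscle Myh10, also on chromosome 11, fell by 1.22, and Myh9 differed by 0.12. On other chromosomes, Myh11 (chromosome 16) was at least 4.03-fold lower with an adjusted p = 0.0206, and Myh7 (chromosome 14) rose by 0.44 with an adjusted p = 0.0399. The directions of Myh1 and Myh8 held under each scaling, with -4.32 and -4.24 under normexp. Normexp shrank the dim genes more, to -1.16 for Myh2, -1.02 for Myh4, -0.733 for Myh11 and -0.472 for Myh13, so the bounds above depend on the background correction.

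A loss of skeletal muscle cells with BMP2 would lower the other muscle genes as well. Of the 11 other muscle genes measured, Acta1 and Tnnt3 fell and Chrna1 rose. The 11 had a median change of 0.178 (SE 0.231), far above the fall of Myh1, which argues against that loss as the cause, although 5 listed muscle genes, Ckm and Mylpf among them, were not tested and 4 of these were above background on no array. Signal of 1 transcript shared by probes of similar genes could give several of these falls. The changes of Myh1 and Myh8 differed by 0.221, within 2 times their summed standard errors, so that shared signal cannot be told apart from a common change.

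Chondrocyte genes were higher with LOXL2, with a median of 0.169 without BMP2 and 0.702 under it, and the list's adjusted p was 0.904 with an estimated correlation. On the same arrays the leukocyte medians were -0.0885 and -0.286, at percentile 2.81 and 0 of random lists, and the tendon and fibroblast medians 0.0101 and -0.0991, at 65.8 and 0.03. Array scaling is argued against, since the median under BMP2 was 0.603 with normexp, 0.698 with quantile normalization and 0.712 with median centring. The lowest value over the other 4 scalings, 0.552 with the deposited values, is given no weight. That setting held 24044 genes against 24041, so its value may come partly from genes outside the list. The list's fitted LOXL2 median with the deposited values was 0.475, against 0.445 in the main fit. A stronger response of all BMP2-raised genes on the combined array was tested by drawing other raised genes with a similar BMP2 change. The 16 raised chondrocyte genes had a median LOXL2 difference of 0.903, at percentile 100 of 10000 such groups, but the 100 genes matched to Matn1, Snorc, Ihh and Col10a1 had a median BMP2 change of 3.13 against 4.35 to 8.33, so this percentile does not decide. For the 12 members with at least 10 other raised genes within 0.2 of their BMP2 change, the median was 0.655, at percentile 99.9 of groups drawn from those genes, the central 95% of whose medians ran from 0.0385 to 0.497. For these 12 this argues against such a response as the whole cause, but with less weight than the percentile gives. The groups were drawn as if genes varied independently. How genes vary together cannot be estimated from 1 residual per gene, so the range of the groups may be too narrow. For the other 4, with a median of 1.30, such a response stays open, as the 10 other genes raised as strongly had a median of 0.613 and ran from -0.135 to 1.53. A difference between cultures, in cell types among others, or array positions that LOXL2 did not make stays open and cannot be told apart from LOXL2, because each treatment was 1 culture, even though the pair without BMP2 also placed the list at percentile 100 of random lists. That LOXL2 adds to the cartilage response under BMP2 is a hypothesis that these 4 arrays do not settle.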
